A study of Homo sapiens with 30 samples.

How the data were processed

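The series held 30 samples from 4 human primary cell populations: CD34+ HSPC of fetal liver (F0) and adult bone marrow (A0), and ProE cultured from each (F5 and A5). Peak lists of 28 samples were analysed, 1 library per antibody and population; 2 input samples were not analysed here. H3K4me1 and H3K27ac lists covered all 4 populations, H3K4me3 and H3K27me3 lists F0, F5 and A0. GATA1, PU.1 and RUNX1 were mapped in F0 and A0, TAL1 and NFE2 in F0, F5 and A0, IRF2 in A0 and GATA2 in A5. Groups were taken from the sample titles.

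Per the labels' protocols, libraries were sequenced on an Illumina HiSeq2500 and only reads with a single alignment to the human genome hg18 were kept. Bowtie 0.12.7 and Picard are named in the submitters' processing notes. The peak names in the deposited lists are those of MACS; its version, control and thresholds are not given in the sources used here. The GATA2 list alone gives all positions rounded, so it may differ from the others in how it was made. Peaks were listed per sample. Each peak carries a score by the authors, deposited on a scale from 0 to 1000 within each list. These scores were used only to rank or filter peaks within a list, since a score in one list has no fixed relation to that in another. The lists give no read counts, so the depth of each library is unknown, and differences in depth or in calling between lists can change how many peaks are shared. Reads with several alignments were left out by the authors, so repeats are under-represented.

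Chromosomes 1 to 22 and X were used. Peaks that touched within a list were merged. Peaks were shared if they overlapped by at least 1 bp, computed with NumPy 2.4.6 in Python 3.11.15; SciPy 1.17.1 gave normal quantiles and matplotlib 3.10.9 drew the plots. The promoter mask was the union of the H3K4me3 peaks of F0, F5 and A0, used for all populations because A5 has no such list among those analysed. An active enhancer was an H3K27ac peak outside the mask that overlapped H3K4me1 of the same population; a primed site was an H3K4me1 peak outside the mask without H3K27ac. An enhancer was kept or shared if it overlapped H3K27ac of the other population.

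Shares are given with Wilson 95% intervals, which cover counting error only. Differences of shares, log2 odds ratios and the logistic slope per factor have 95% intervals from 1000 resamples of 616 genome blocks of 5 Mb, with the same resamples for the fetal and adult values, so that their difference is paired. A difference was called when this interval excluded 0. It describes these libraries along the genome, not donors, so no p-values are given. The 11 log2 odds ratios of kept against lost enhancers and the 11 of primed sites were each adjusted as a family by widening the interval (Bonferroni). Overlaps of lists were set against 100 circular shifts of one list along each chromosome, by 5 to 95% of its length, and called when above all of them.

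At 1 bp the overlap code gave the same number of shared peaks as bedtools 2.31.1 for 5 of 5 pairs of lists. The 50% rule added up the cover by all peaks of the other list, whereas bedtools asks it of a single peak, so the counts of that rule can be higher. The code was tested on simulated data, with binding drawn 100 times for the 15108 F0 enhancers. For a true log2 odds ratio of 1 the mean estimate was 0.996 and 94 of the 100 intervals held the truth; for 0 the mean was -0.0081 and 93 did. Where binding also rose with width, the unstratified estimate was 1.55 for a true value of 1, and the width-stratified one 1.03. For a true value of 0 these were 0.60 and 0.038, and 90 of the 100 stratified intervals held the truth. The stratified slope was not simulated. For the 6 odds ratios of GATA1, NFE2 and RUNX1, binding was also drawn 100 times from a logistic fit on enhancer width or score alone, a test chosen after the stratified values were seen. The bins then left over a mean log2 odds ratio of at most 0.075 for width and 0.030 for score. For 4 pairs of lists, 1 list of the pair was shifted another 50 times. Among these 200 further shifts, 4 exceeded all 100 shifts, and the highest ratio over the shift mean was 2.41. All 4 were among the 50 for RUNX1 with NFE2 in F0. The other pairs were added after that result was seen. The further shifts follow the same model as the 100, so they check the code but not whether shifts suit clustered peaks.

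The comparisons, the alternatives and the rule for the regions named were fixed before the data were examined: the 3 peaks of each class with the highest score, ties by width and then position, and the 3 enhancers bound by most factors. Other settings tried were an overlap of at least 50% of the query peak, only peaks at or above the median score of each list or of the query list, a mask extended by 2000 bp, lists of equal length, enhancers with or without H3K4me1, draws from marked regions and blocks of 1 Mb. Stratification by 10 bins of width or score and a count of factors without GATA1 and TAL1 were added after the data were seen, as were the comparisons of F5 factors by enhancer history and of HSPC factors by origin. Gene annotation and genome sequence in hg18 were not used here, so regions are given by coordinates, and genes, gene lists and motifs were not analysed here.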

Results

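Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 4 histone modifications and 7 transcription factors in 4 human blood cell populations. The populations were CD34+ hematopoietic stem and progenitor cells (HSPC) from fetal liver (F0) and from adult bone marrow (A0), and the proerythroblasts (ProE) obtained from each in culture (F5 and A5). H3K4me1 marks enhancers in general, H3K27ac marks active enhancers and promoters, H3K4me3 marks promoters, and H3K27me3 is laid down by Polycomb at silenced genes. Each of the 28 peak lists came from 1 library, so nothing measured the spread between donors or cultures. Intervals therefore cover counting error or the spread along the genome only, and sequencing depth was unknown from the peak lists.

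The H3K27ac lists held 32908 peaks in F0, 32572 in F5, 32469 in A0 and 31317 in A5. Peaks at the promoter mask, the union of the H3K4me3 peaks of F0, F5 and A0, made up 48.1% of them in F0, 47.8% in F5, 51.9% in A0 and 51.7% in A5. An active enhancer was an H3K27ac peak outside this mask with H3K4me1 in the same population. This gave 15108 enhancers in F0, 13768 in F5, 13800 in A0 and 13209 in A5. Distal H3K27ac without H3K4me1 was 9.90% of the peaks in F5 (Wilson 95% interval 9.58 to 10.2%) and lay between 5.62% and 6.15% in the other populations.

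The first comparison asked how far the enhancers of HSPC stayed active in ProE. Of the F0 enhancers, 29.4% (28.7 to 30.1%) carried H3K27ac in F5, and of the A0 enhancers, 31.0% (30.2 to 31.8%) carried it in A5. Promoter peaks were kept far more often, 82.8% from F0 to F5 and 83.9% from A0 to A5. The promoter share exceeded the enhancer share by 53.4 percentage points in the fetal pair (genome-block bootstrap 95% interval 52.2 to 54.5) and by 52.9 points in the adult pair (51.8 to 54.0). Because the mask includes H3K4me3 of F5, F0 peaks with that mark only in F5 counted as promoter peaks. How far this widens the gap was not tested. The fetal and adult gaps differed by 0.506 points, with an interval from -0.629 to 1.65 that included 0. Among peaks at or above the median score of the query list, this difference turned to -2.46 points (-4.22 to -0.458), whereas it rose to 1.55 (0.466 to 2.61) with an overlap of at least 50% and to 1.51 (0.0123 to 3.08) with all lists limited to peaks at or above their median. Shifted along the chromosomes, F0 enhancers met F5 H3K27ac in 5.19% of cases on average. The share kept depended on peak strength. Among HSPC enhancers from the H3K27ac peaks at or above the median score of their list, 49.9% were kept from F0 to F5 and 48.4% from A0 to A5.

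The same enhancers were then followed between fetal and adult cells at a matched stage, where far more were shared. H3K27ac was found in A0 at 65.1% (64.3 to 65.9%) of the F0 enhancers, and in F0 at 72.9% (72.1 to 73.6%) of the A0 enhancers. At the ProE stage, 59.2% of the F5 enhancers had H3K27ac in A5 and 64.0% of the A5 enhancers had it in F5. The share kept through differentiation minus the share found in the other origin was -35.7 points for F0 enhancers (-36.9 to -34.5), -41.9 for A0 (-43.3 to -40.3), -30.0 for F5 (-31.6 to -28.4) and -31.4 for A5 (-33.2 to -29.5). All 4 intervals excluded 0.

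**Figure D1:**
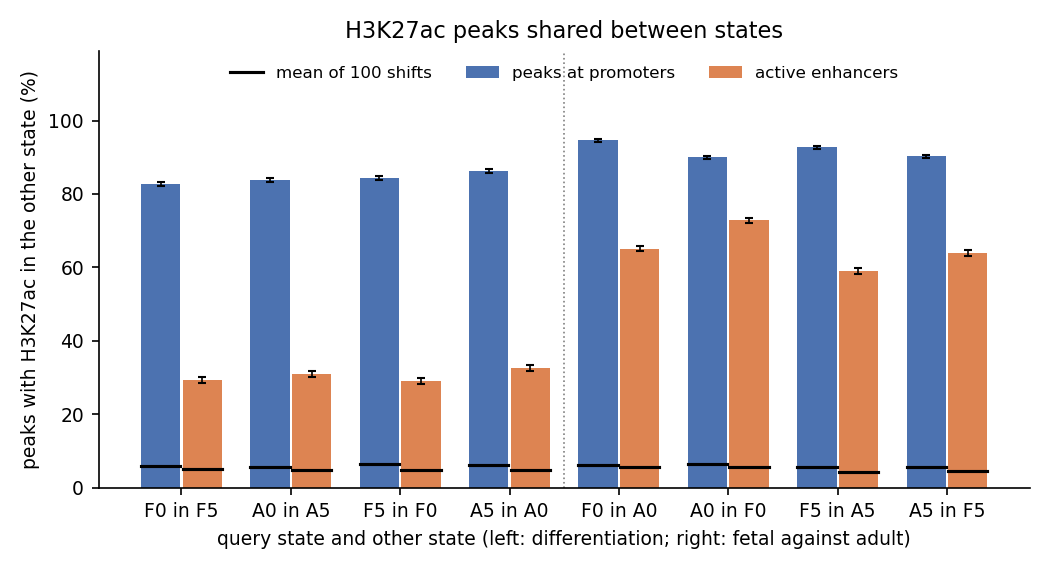
Share of H3K27ac peaks of a query state (percent, y axis) that overlapped H3K27ac of another state (x axis), for peaks at promoters and for active enhancers. Bars carry Wilson 95% intervals and black lines give the mean of 100 circular shifts. Enhancers were shared at 29.1 to 32.6% across differentiation and at 59.2 to 72.9% between fetal and adult cells, whereas the lowest share of promoter peaks among the pairs drawn was 82.8%.

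Merged over the populations, the enhancers formed 32533 regions. H3K27ac was present in all 4 populations at 2831 regions (8.70%), in both HSPC populations only at 5527 (17.0%) and in both ProE populations only at 4948 (15.2%). A single population held the mark at 4454 regions in F0, 4140 in F5, 3407 in A5 and 2497 in A0. Regions shared by F0 and F5 alone numbered 558, and those shared by A0 and A5 alone 521.

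**Figure D2:**
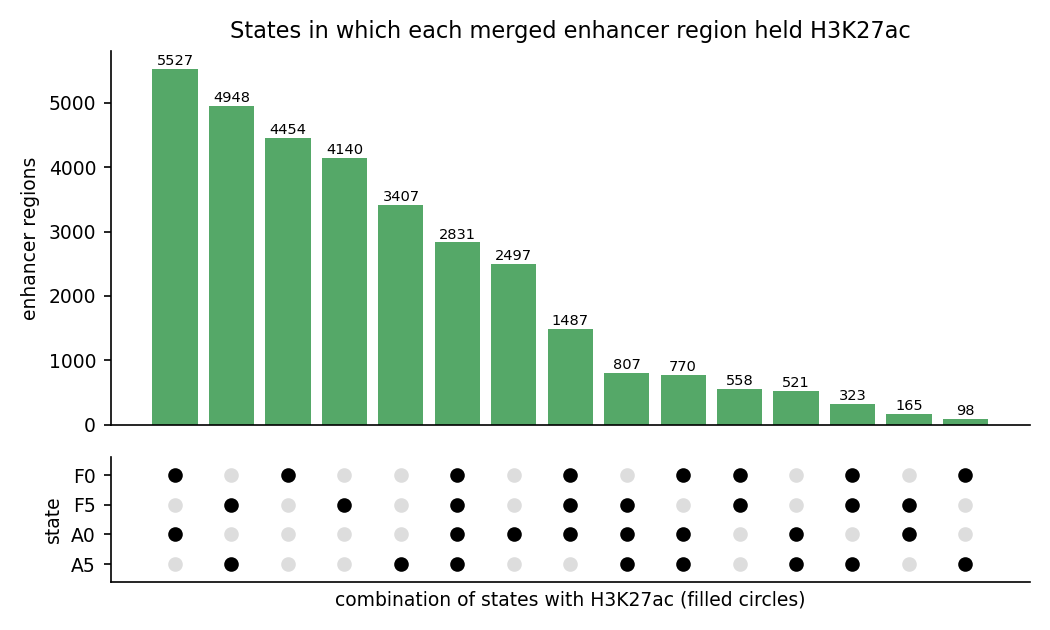
Number of merged enhancer regions (y axis) for each combination of states with H3K27ac (filled circles, x axis), ordered by number. The combinations of both HSPC states (5527) and of both ProE states (4948) led, and 2831 regions held the mark in all 4 states.

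Regions were named by the authors' score within a list, ties by width, and are given in hg18. Their genes were not analysed here. Among F0 enhancers without H3K27ac in F5, the highest scores belonged to chromosome 5 at 126075884 to 126080127, chromosome 17 at 42502258 to 42506416 and chromosome 14 at 68129219 to 68132398, and all of them had PU.1 peaks in F0 and A0. Among F5 enhancers absent from F0, chromosome 22 at 23825659 to 23828504, chromosome X at 123309225 to 123310883 and chromosome 5 at 149385631 to 149388130 ranked highest, each with a TAL1 peak in F5 and with H3K27ac in A5. The strongest A0 enhancers lost in A5 lay on chromosome 1 at 114455674 to 114459638, chromosome 2 at 64931227 to 64936328 and chromosome 14 at 92617556 to 92623586, each with PU.1 peaks in F0 and A0 and with H3K27ac in F0. The strongest A5 enhancers absent from A0 lay on chromosome 3 at 171138678 to 171142013, chromosome 6 at 41921445 to 41923306 and chromosome 3 at 159367408 to 159370112, and each also had H3K27ac in F5.

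Origin-restricted regions were named by the same rule. F0 enhancers without H3K27ac in A0 were led by chromosome 1 at 156521011 to 156524420, chromosome 9 at 133485399 to 133487933 and chromosome 10 at 71927934 to 71931686, all with H3K4me1 in A0 and H3K27ac in no population but F0. A0 enhancers without H3K27ac in F0 were led by chromosome 1 at 3420863 to 3425536, chromosome 6 at 156515687 to 156520278 and chromosome 22 at 28457861 to 28462444. F5 enhancers without H3K27ac in A5 were led by chromosome 4 at 82896375 to 82899369, chromosome 3 at 119647965 to 119650218 and chromosome 2 at 170776773 to 170779776, and a TAL1 peak of F5 lay in each. A5 enhancers without H3K27ac in F5 were led by chromosome 5 at 79536171 to 79539659, chromosome 17 at 3560677 to 3563789 and chromosome 5 at 171995369 to 171999047. F0 enhancers with H3K27ac in all 4 populations were led by chromosome 16 at 28059077 to 28066473, chromosome 6 at 37114018 to 37120114 and chromosome 5 at 109017618 to 109022543.

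The marks around a change of enhancer state were read from the other lists. Of the 10669 F0 enhancers without H3K27ac in F5, 29.3% (28.5 to 30.2%) still had H3K4me1 in F5, 2.72% had H3K27me3 without H3K4me1, and 68.0% had neither mark. In the adult pair, 28% (27.1 to 28.9%) of the 9524 lost enhancers kept H3K4me1. Of the 9757 F5 enhancers without H3K27ac in F0, 17.2% (16.4 to 17.9%) already had H3K4me1 in F0, and 82.0% had neither H3K4me1 nor H3K27me3. Prior H3K4me1 was found at 25.2% (24.3 to 26.1%) of the 8901 enhancers gained in A5; the difference between fetal and adult cells was not tested. With only the peaks at or above each list's median score, the gained enhancers numbered 4137 in F5 and 3431 in A5. Distal H3K4me1 sites without H3K27ac, called primed here, numbered 19894 in F0 and 18067 in A0. H3K27ac was present in the ProE of the same origin at 8.33% (7.95 to 8.72%) of the F0 sites and 9.21% (8.80 to 9.64%) of the A0 sites. These shares, and those of prior H3K4me1, were not set against shifts. For scale, shifted enhancers met H3K27ac on average in 5.19% of cases from F0 to F5 and 4.86% from A0 to A5.

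Factors bound in HSPC were compared between enhancers kept and lost in ProE. GATA1, TAL1 and NFE2 are regulators of erythroid genes, PU.1 drives myeloid and lymphoid fates, RUNX1 is needed for the formation of blood stem cells, and IRF2 is an interferon regulatory factor. In F0, GATA1 was bound at 12.7% of kept and 7.29% of lost enhancers, NFE2 at 10.7% and 6.0%, and RUNX1 at 20.6% and 12.2%. The log2 odds ratios were 0.89 (bootstrap 95% interval 0.72 to 1.06) for GATA1, 0.90 (0.70 to 1.09) for NFE2 and 0.90 (0.76 to 1.05) for RUNX1. In A0, TAL1 had the highest value, 1.22 (0.94 to 1.49), with 5.38% of kept and 2.38% of lost enhancers bound. RUNX1 stood at 1.06 (0.89 to 1.22), NFE2 at 0.97 (0.83 to 1.12) and GATA1 at 0.94 (0.70 to 1.18). These 7 odds ratios also excluded 0 after adjustment over the family of 11. Fetal minus adult, the log2 odds ratio of TAL1 differed by -0.86 (-1.20 to -0.50), while the intervals for GATA1 (-0.053, -0.36 to 0.25), NFE2 (-0.070, -0.30 to 0.14) and RUNX1 (-0.15, -0.36 to 0.050) included 0. The RUNX1 difference excluded 0 with peaks at or above each list's median (-0.47, -0.77 to -0.17), with the extended mask (-0.23, -0.43 to -0.023) and for enhancers with or without H3K4me1 (-0.24, -0.44 to -0.041).

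PU.1 occupied more enhancers than any other factor in both HSPC populations but separated kept from lost ones little. It was bound at 40.8% of kept and 37.2% of lost F0 enhancers (log2 odds ratio 0.22, 0.11 to 0.33) and at 34.9% and 35.0% in A0 (-0.0028, -0.12 to 0.11). TAL1 in F0 reached 0.36 (0.060 to 0.64) and IRF2 in A0 0.61 (0.14 to 1.09), and neither passed the adjustment over the family. The fetal minus adult difference for PU.1 was 0.22 (0.092 to 0.36). Bound enhancers were wider, so the odds ratios were recomputed within bins of enhancer width and of H3K27ac score, a choice made after the data were seen. Within width bins they were 0.40 for GATA1, 0.43 for NFE2, 0.21 for RUNX1, -0.15 for TAL1 and -0.24 for PU.1, and within score bins 0.51, 0.30, 0.068, -0.28 and -0.41 in the same order. In A0 within width bins, TAL1 stood at 1.17, GATA1 at 0.81, NFE2 at 0.75, RUNX1 at 0.64 and PU.1 at -0.35, and within score bins RUNX1 stood at 0.52 and PU.1 at -0.50. RUNX1 in F0 was not called within score bins, nor TAL1 in F0 within either. Within width bins the fetal minus adult differences of GATA1 (-0.41), NFE2 (-0.31) and RUNX1 (-0.44) excluded 0, and that of PU.1 (0.11) no longer did. Within score bins those of NFE2 (-0.36) and RUNX1 (-0.45) excluded 0, but those of GATA1 (-0.29, -0.61 to 0.034) and PU.1 (0.093, -0.055 to 0.24) did not.

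**Figure D3:**
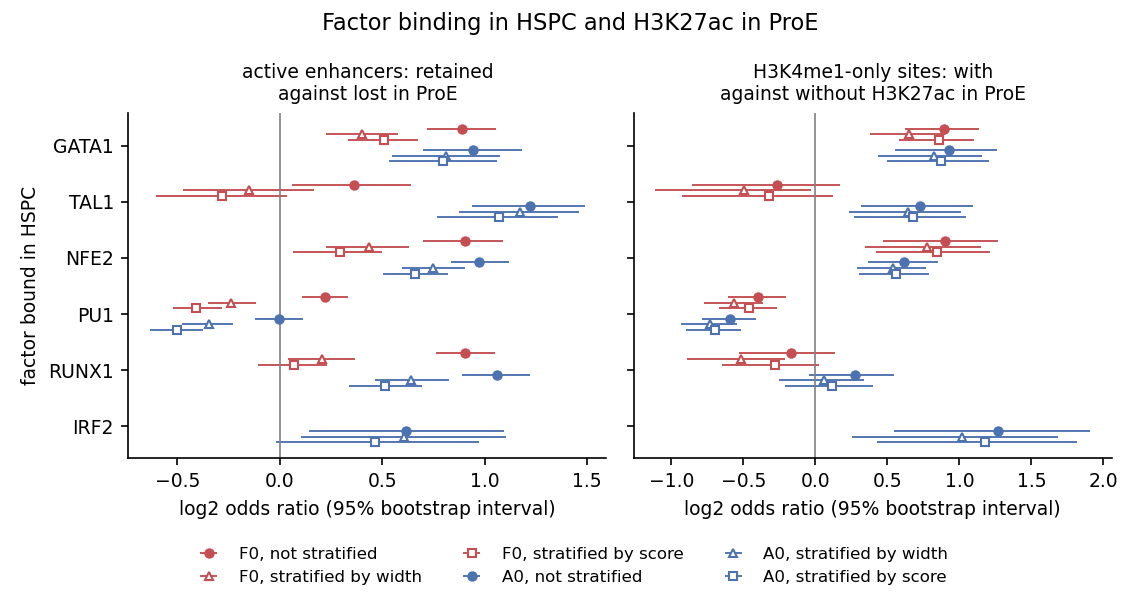
Log2 odds ratios (x axis, with 95% genome-block bootstrap intervals) of factor binding in HSPC (y axis), for kept against lost enhancers on the left and for primed sites with against without H3K27ac in ProE on the right. Filled circles are unstratified, triangles are within bins of width and squares within bins of score, in red for F0 and blue for A0; PU.1 in F0 moved from 0.22 to -0.24 within width bins and to -0.41 within score bins.

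The number of factors bound, out of the 5 mapped in both HSPC populations, was set against the share of enhancers kept. In F0 it rose from 25.2% of the 7112 enhancers without any factor to 39.2% of 1915 with 2 factors and 50.2% of 434 with 3. In A0 it rose from 27% of 6798 to 42.6% of 1522 and 57.1% of 275. The log2 odds of being kept rose per factor by 0.47 (0.41 to 0.54) in F0 and 0.51 (0.43 to 0.58) in A0, and the difference between them, -0.034 (-0.11 to 0.048), included 0. Median enhancer width grew along with the number, from 1863 bp without any factor to 3621 bp with 3 factors in F0. Within width bins the slope was 0.055 (-0.022 to 0.13) in F0 and 0.27 (0.19 to 0.34) in A0, and within score bins -0.040 (-0.12 to 0.044) and 0.17 (0.086 to 0.25). The rise in F0 was therefore not called at matched width or score, and the fetal minus adult difference became -0.21 within either kind of bin, with intervals below 0.

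At primed sites, GATA1 and NFE2 binding in HSPC went with H3K27ac in ProE. GATA1 was bound at 9.11% of the F0 sites that gained the mark and 5.13% of the others (log2 odds ratio 0.90, 0.62 to 1.14), and in A0 the odds ratio was 0.93 (0.55 to 1.26). NFE2 reached 0.90 (0.47 to 1.27) in F0 and 0.62 (0.36 to 0.85) in A0. PU.1 was bound less often at the sites that gained the mark, 17.4% against 21.7% in F0 (-0.40, -0.61 to -0.21) and 16.9% against 23.6% in A0 (-0.59, -0.79 to -0.41). TAL1 was positive in A0 (0.73, 0.32 to 1.10) but not called in F0 (-0.27, -0.86 to 0.17). RUNX1 was called in neither (-0.17 in F0, 0.27 in A0). Fetal minus adult, TAL1 differed by -1.0 (-1.70 to -0.39) and RUNX1 by -0.45 (-0.88 to -0.030), and the intervals for GATA1, NFE2 and PU.1 included 0. The RUNX1 difference was not called with an overlap of at least 50% (-0.38, -0.79 to 0.0040) or within score bins (-0.39, -0.85 to 0.035). IRF2 in A0 reached 1.27 (0.54 to 1.91) on 20 bound sites among the 1664 that gained the mark. The called values within F0 and within A0 passed the family adjustment as well. Within width bins, the F0 values of RUNX1 (-0.52) and TAL1 (-0.50) also excluded 0.

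In fetal ProE, binding of TAL1 and NFE2 differed by the history of the enhancers, a comparison added after the data were seen. The odds ratios of this paragraph were not recomputed within bins of width or score. Enhancer width or strength may therefore account for part or all of them. TAL1 occupied 43.7% of the enhancers gained over F0 and 27.9% of those shared with F0 (log2 odds ratio 1.0, 0.87 to 1.13). NFE2 showed the opposite order, 12.9% of gained and 29.9% of shared enhancers (-1.53, -1.68 to -1.40). Both were rare at lost F0 enhancers, TAL1 at 3.53% and NFE2 at 5.63%. Both were also bound less often at F5 enhancers without H3K27ac in A5 than at those with it, TAL1 at 29.9% against 45.4% (-0.96, -1.08 to -0.85) and NFE2 at 12.3% against 21.6% (-0.97, -1.12 to -0.81). Among A0 enhancers, PU.1 occupied 18.3% of those without H3K27ac in F0 and 41.2% of those with it (-1.64, -1.78 to -1.50). In F0 the corresponding PU.1 shares were 35.6% and 39.6% (-0.24, -0.34 to -0.14). The log2 odds ratios of the other factors in F0 were -1.05 for NFE2, -1.05 for RUNX1, -0.62 for TAL1 and -0.46 for GATA1, all with intervals below 0. In A0, RUNX1 (-1.04, -1.28 to -0.82) and NFE2 (-0.52, -0.69 to -0.36) were also lower without H3K27ac in F0, whereas GATA1 (0.32, 0.017 to 0.58) and TAL1 (0.38, 0.080 to 0.65) were higher and IRF2 (0.10, -0.46 to 0.64) was not called.

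Factor peaks were placed by the promoter mask and then by the other marks of their own population. In F5, NFE2 lay at the promoter mask in 63.7% (63.0 to 64.4%) of its 17373 peaks, whereas TAL1 lay mainly outside it, with 29.2% of its 20156 peaks in active enhancers and 34.0% at H3K4me1 alone. In HSPC, most GATA1 and TAL1 peaks carried none of the marks, 66.3% and 70.7% in F0 and 77.3% and 76.1% in A0. PU.1 peaks were unmarked in 45.3% (F0) and 51.9% (A0), NFE2 peaks in 52.6% and 52.0%, RUNX1 peaks in 30.3% and 47.8%, and IRF2 peaks of A0 in 78.3%. H3K27me3 alone marked at most 4.19% of the peaks of any factor in F0, F5 or A0.

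**Figure D4:**
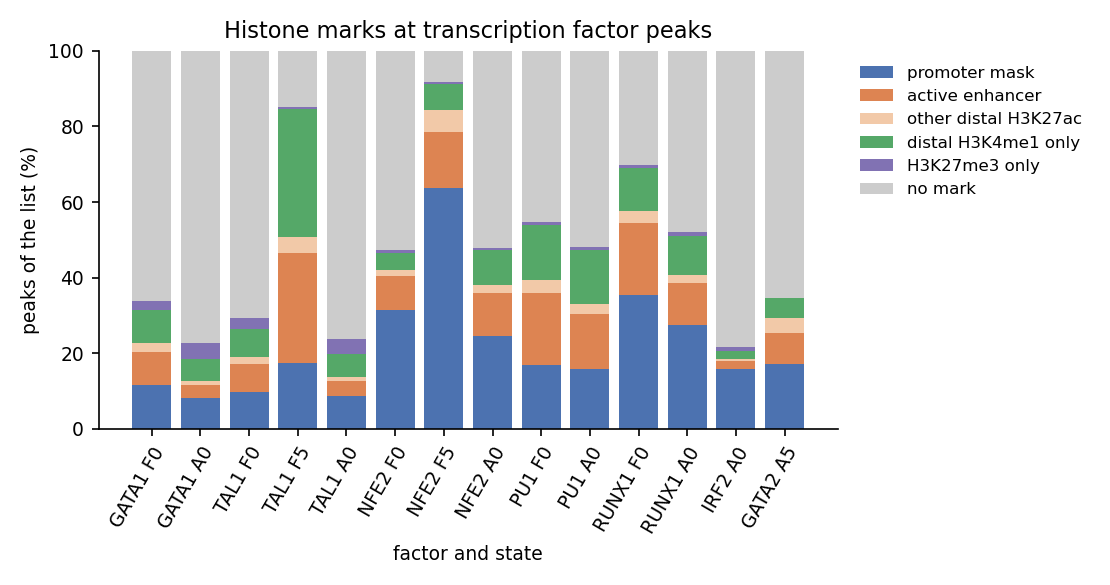
Share of the peaks of each factor list (percent, y axis) by histone mark, for each factor and state (x axis). Each peak was counted in the first class it met from the bottom of the bar up. The promoter class was the mask made from F0, F5 and A0. Other marks were those of the same state, which lacked H3K27me3 in A5. Unmarked peaks made up 8.25% of NFE2 in F5 and 78.3% of IRF2 in A0.

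Binding was next compared between fetal and adult HSPC. PU.1 had the highest share in both directions, with 73.0% (72.5 to 73.5%) of its 33580 F0 peaks present in A0, against 52.3% (51.4 to 53.2%) for NFE2 and 43.3% (42.5 to 44.2%) for RUNX1. Of the A0 peaks, 68.7% for PU.1, 34.0% for NFE2 and 44.5% for RUNX1 lay in the F0 list, so the order of NFE2 and RUNX1 depended on the direction. GATA1 and TAL1 lists barely met, at 1.26% (1.10 to 1.45%) of 16249 and 0.622% (0.468 to 0.826%) of 7555 F0 peaks. Within 1 kb of an A0 peak these shares were 3.35% (3.09 to 3.64%) and 2.0% (1.71 to 2.34%), against 74.2% for PU.1. All of the overlaps exceeded all 100 circular shifts, which gave at most 0.228% for GATA1 and 0.251% for TAL1. From F0 to F5, 29.7% (28.9 to 30.5%) of NFE2 peaks and 4.58% (4.13 to 5.07%) of TAL1 peaks were found again. In the highest-scoring decile of the F0 peaks the share found in A0 reached 97.5% for PU.1, 97.1% for NFE2 and 93.0% for RUNX1, against 2.52% for GATA1 and 0.397% for TAL1. Of the peaks in that decile, 80.3% for PU.1, 50.6% for NFE2 and 56.6% for RUNX1 overlapped H3K4me1, H3K27ac or H3K4me3 of F0. The labels name the same antibody for a factor in both populations.

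**Figure D5:**
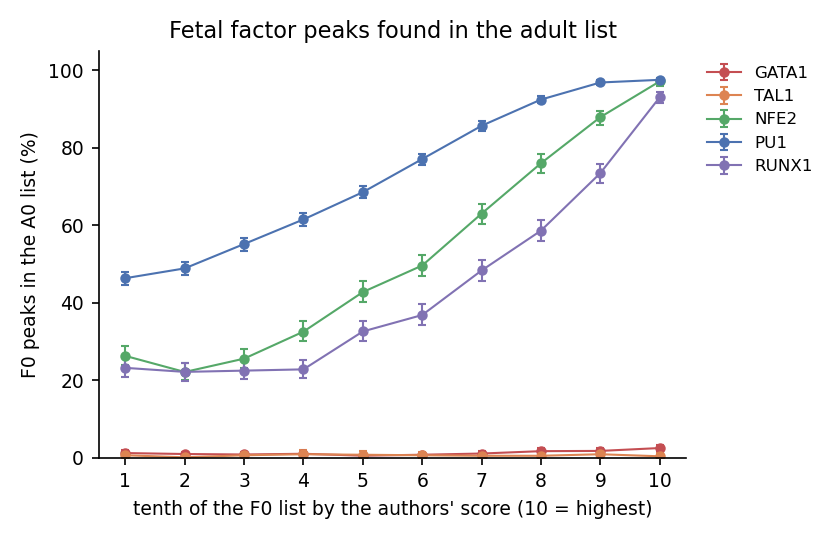
Share of F0 factor peaks found in the A0 list of the same factor (percent, y axis) by decile of the F0 list in the authors' score (x axis, 10 the highest), with Wilson 95% intervals. PU.1, NFE2 and RUNX1 rose to between 93.0 and 97.5%, whereas GATA1 and TAL1 stayed at or below 2.52%.

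Pairs of factors were tested for shared peaks in the same population. All 26 pairs overlapped more often than in any of the 100 shifts. The largest ratios over the shift mean were 158 for RUNX1 with IRF2 in A0, 104 for NFE2 with RUNX1 in F0, 99.9 for NFE2 with IRF2 in A0 and 76.6 for NFE2 with RUNX1 in A0. GATA1 with TAL1 reached 23.4 in F0 and 20.6 in A0, although only 291 and 357 GATA1 peaks were involved. TAL1 with NFE2 in F5 reached 29.0. Of the 3134 IRF2 peaks without any histone peak that were shared with RUNX1 or NFE2 in A0, 57.8% lay within 0.5 Mb of a stretch of 1 Mb or more without histone peaks. Against random draws from regions carrying a mark, the ratios were lower, from 1.24 to 2.89, with GATA1 and TAL1 in A0 highest, and each still exceeded its draws. These draws took no account of region width, and enhancers with more factors were wider. Region width alone may therefore lift these ratios above 1. Regions bound by most factors were, in F0, chromosome 1 at 59132181 to 59139257 and chromosome 12 at 112780414 to 112786498 with all 5, and chromosome 1 at 27815268 to 27819032 with 4. In A0 they were chromosome 1 at 10396417 to 10400847, chromosome 13 at 31578448 to 31592959 and chromosome 15 at 29340663 to 29348881, with 5 each.

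Promoters with both H3K4me3 and H3K27me3, called bivalent, made up 25.7% (25.2 to 26.3%) of the H3K4me3 peaks in F0, 23.9% (23.3 to 24.5%) in A0 and 20.9% (20.3 to 21.4%) in F5. The call is an overlap of separate lists from whole populations, so whether both marks lay in the same cells is unknown. Of the 5411 bivalent F0 peaks, 58.7% (57.4 to 60%) held both marks in F5, 37.0% (35.7 to 38.3%) held H3K27me3 without H3K4me3 and 4.16% held H3K4me3 without H3K27me3. Between fetal and adult HSPC, 79.6% stayed bivalent. H3K27ac lay at 17.5% of the bivalent F0 peaks and at 86.5% of those with H3K4me3 alone. The bivalent share fell to 15.4% in F0, 15.0% in F5 and 10.9% in A0 when only peaks at or above each list's median score were used. H3K27me3 covered 55.8 Mb in F0, 59.9 Mb in A0 and 76.3 Mb in F5.

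GATA2, a stem and progenitor cell factor, was mapped in adult ProE alone and gave 571 peaks. Of these, 17.2% (14.3 to 20.5%) lay at the promoter mask and 8.23% (6.25 to 10.8%) in active A5 enhancers. Another 65.3% lay at neither the mask nor H3K4me1 or H3K27ac of A5. H3K27me3 was not among the marks listed for A5. H3K27ac of A5 overlapped 25.9% of the peaks, 8.93 times the shift mean. Among factors, RUNX1 of F0 overlapped 25.7% of the peaks, TAL1 of F5 22.9%, NFE2 of F0 22.6%, RUNX1 of A0 21.2%, NFE2 of F5 20.5%, NFE2 of A0 19.4% and IRF2 of A0 17.0%, or 152, 56.5, 133, 104, 35.5, 61.0 and 190 times the shift mean. The overlap of 3 peaks with TAL1 in A0 did not exceed all shifts. Of the GATA2 peaks, 24.0% (20.7 to 27.7%) lay within 0.5 Mb of a stretch of 1 Mb or more without histone peaks. GATA2 peaks with the highest scores lay on chromosome X at 48534291 to 48535960 and at 48536341 to 48537670, and on chromosome 12 at 123964081 to 123965630, and all of them lay within H3K27ac of F5 and A5. With only peaks at or above each list's median score, the shares were 5.76% at the promoter mask and 5.08% in active enhancers.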

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

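The tests of the GATA1 and TAL1 lists by score and by background were chosen only after the overlap had been seen, and the stratification by width or score only after the odds ratios had been seen. All differences below are between single libraries.

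Fetal and adult cells differed for TAL1 in both settings. The log2 odds ratio of TAL1 binding at kept against lost enhancers was 0.36 in F0 and 1.22 in A0, a difference of -0.86 (-1.20 to -0.50), and at primed sites the difference was -1.0 (-1.70 to -0.39). Within width bins these differences were -1.32 and -1.14, and both intervals stayed below 0. PU.1 at kept against lost enhancers differed by 0.22 (0.092 to 0.36), which became 0.11 (-0.024 to 0.26) within width bins. RUNX1 at primed sites differed by -0.45 (-0.88 to -0.030), which became -0.39 (-0.85 to 0.035) within score bins and -0.38 (-0.79 to 0.0040) with an overlap of at least 50%.

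The TAL1 difference rests on lists that barely share peaks, and the same holds for GATA1. If the A0 lists hold the sites bound there, peaks near the calling threshold of the F0 lists are argued against. Only 2.52% (1.87 to 3.41%) of the highest-scoring decile of GATA1 F0 peaks, and 0.397% (0.135 to 1.16%) of that of TAL1, lay in the A0 list. On the same condition, a different set of active enhancers in fetal and adult HSPC is argued against too. Where H3K27ac was present in both, 48 (5.0%, 3.79 to 6.57%) of the 960 enhancers bound by GATA1 in F0 were bound in A0. For TAL1 it was 4.11% (2.55 to 6.58%) of 389. Of all 10055 A0 enhancers with H3K27ac in F0, GATA1 was bound in A0 at 342 (3.40%) and TAL1 at 309 (3.07%). So few sites capped the GATA1 share of the 960, although 48 lay well below that cap. The condition itself stays open. Without it, the shares of F0 peaks and F0-bound enhancers found in A0 would be low whatever the cause. Background spread evenly along the genome is argued against as the whole of the F0 lists. Their peaks met marked regions 5.09 (GATA1) and 4.28 (TAL1) times as often as shifted peaks. Shifts cannot tell binding from background that itself favours marked regions, and the input samples were not analysed. Such background stays open for F0, where 54.6% of GATA1 and 62.6% of TAL1 peaks overlapped no histone peak of any population. The A0 ratios of 2.74 and 2.98 fell between the limits set and leave any background in the A0 lists open. Donor, culture and chromatin quality cannot be separated from origin with 1 library each, and a real difference in binding between fetal and adult HSPC may remain, untested.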

How the results depend on the processing

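Stratification by width or score and the count without GATA1 and TAL1 were chosen after the data were seen; all other settings were chosen before. The 4 differences between differentiation and origin kept their direction and their call under each setting run for them, as did the 26 pairs of factors and the 14 overlaps of factor lists between states under theirs. The promoter excess stayed called throughout, from 36.6 to 63.0 points in the fetal and 37.3 to 61.5 in the adult pair. The lowest value of each pair was that within score bins. Where a value changed, the cause was not tested, except that fewer peaks per list leave fewer enhancers. The depth of the libraries is unknown, so how far depth limits the shares is open.

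With an overlap of at least 50%, enhancers kept were 22.6% (F0 in F5), 25.3% (A0 in A5) and 57.5% (F5 in A5); log2 odds ratios were 0.22 for TAL1 in F0 and 0.064 for PU.1 in F0, no longer called, and -0.22 for PU.1 in A0, now called. Prior H3K4me1 was 15.9% in F5, bivalent shares were 22.7% (F0), 18.8% (F5) and 21.2% (A0), and the fetal minus adult promoter gap was 1.55, now called. With only peaks at or above each median, enhancers kept were 24.1% (F0 in F5), 66.1% (F0 in A0), 61.7% (F5 in A5) and 26.9% (A0 in A5); IRF2 was 0.37, no longer called. Prior H3K4me1 was 14.4% in F5 and 23.5% in A5 for 4137 and 3431 gained enhancers, bivalent shares were 15.4%, 15.0% and 10.9%, and GATA2 shares 5.76% at the mask and 5.08% at enhancers; the promoter gap was 1.51 and RUNX1 at kept against lost enhancers, fetal minus adult, -0.47, both now called. With the query list alone at or above its median, the shares were 49.9%, 90.1%, 83.9% and 48.4% in the same order, and the fetal minus adult promoter gap turned to -2.46.

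With the extended mask, A0 in A5 was 29.8%, prior H3K4me1 15.4% in F5 and 22.6% in A5, GATA2 at the mask 20.5%, and RUNX1 at primed A0 sites 0.35 and at kept against lost enhancers, fetal minus adult, -0.23, both now called. Equal list lengths gave 65.9% (F0 in A0), 61.3% (F5 in A5) and 31.9% (A0 in A5). Without the need for H3K4me1 the shares were 62.8% (F0 in A0) and 52.5% (F5 in A5), and the same RUNX1 difference was -0.24, now called. Blocks of 1 Mb changed no call. Of the 28 shares of factor peaks at promoters or enhancers, 15 moved beyond their interval with the 50% overlap, 25 with the stricter lists and 24 with the extended mask.

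Within width bins at kept against lost enhancers, TAL1 in F0 turned to -0.15 and PU.1 in F0 to -0.24, and PU.1 in A0 was -0.35, now called. At primed F0 sites TAL1 was -0.50 and RUNX1 -0.52, both now called, and the slope per factor in F0 was 0.055, no longer called. Within score bins, TAL1 in F0 turned to -0.28, PU.1 in F0 to -0.41 and the slope in F0 to -0.040; RUNX1 in F0 (0.068) and IRF2 (0.47) were no longer called, and PU.1 in A0 was -0.50. Without GATA1 and TAL1 the slopes were 0.46 and 0.44. Primed sites without the need for H3K4me1 and gene windows were not run, since primed sites are defined by H3K4me1 and genes were not analysed here.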

Other observations

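The tests of co-binding outside marked chromatin, of enhancer width and score, and with simulated binding were chosen only after the patterns had been seen.

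Many PU.1 sites outside all histone marks mapped here were shared by F0 and A0. Of the F0 PU.1 peaks, 13492 (40.2%) overlapped no histone peak of any population, and 66.4% (65.6 to 67.2%) of these were found again in A0, against 77.4% (76.8 to 78.0%) of the marked ones. The same shares were 43.6% and 60.6% for NFE2, 52.8% and 39.9% for RUNX1, and 0.722% and 1.91% for GATA1. From A0 to F0 they were 56.1% and 78.9% for PU.1, 30% and 37.3% for NFE2, and 32.5% and 53.7% for RUNX1, so the order within RUNX1 depended on the direction. Unmarked PU.1 peaks of F0 lay near long stretches without histone peaks in 10.8% of cases, compared with 37.1% for NFE2, 46.2% for RUNX1, 7.89% for GATA1 and 9.01% for TAL1.

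Wide H3K27ac domains of at least 10 kb numbered 423 in F0, 559 in F5, 416 in A0 and 386 in A5, and 77.8 to 92.0% of them touched the promoter mask. At 97.6% (95.7 to 98.7%) of those in F0, at least 50% of the bases carried H3K27ac in A0, against 58.2% (53.4 to 62.8%) in F5. Of the 559 in F5, 132 had no H3K27ac in F0 and 3 had none in A5. The widest, chosen after its values were seen, spanned 55952 bp on chromosome 10 at 126352842 to 126408793 in F5. The widest H3K27me3 peak in F0, on chromosome 12 at 52627473 to 52722013, held the mark over 94499 of its 94541 bp in F5 and over all of it in A0.

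Among the 571 GATA2 peaks, 191 lay at H3K4me1 or H3K27ac of A5, and 64.4% (57.4 to 70.8%) of these 191 overlapped TAL1 of F5, against 2.11% (1.07 to 4.10%) of the other 380. The GATA2 list had 59 peaks (10.3%) at unmarked sites shared by IRF2, RUNX1 and NFE2 in A0.

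NFE2, RUNX1 and IRF2 also coincided outside marked chromatin: 54.1% of the 5794 unmarked IRF2 peaks lay in the RUNX1 or NFE2 list of A0. Unspecific signal beside the 162 stretches of 1 Mb or more without any histone peak is a candidate explanation: the shared unmarked IRF2 peaks lay within 0.5 Mb of one in 57.8% of cases, 13.6 times the share of unmarked GATA1 peaks in A0 (4.25%, the lowest of the A0 lists; 9.77% for PU.1). Such signal would also count among the NFE2 and RUNX1 peaks shared by F0 and A0. Of the 2096 unmarked sites of all 3 factors, 86.6% (85.1 to 88.0%) also lay in the F0 RUNX1 or NFE2 list. At most of these sites, RUNX1 or NFE2 signal was thus not particular to adult HSPC. IRF2 was not mapped in F0, so IRF2 binding or co-binding particular to adult HSPC could not be tested. The sites were selected for peaks in all 3 A0 lists. Among all unmarked A0 peaks, only 30% for NFE2 and 32.5% for RUNX1 lay in the F0 list of the same factor. Real binding of NFE2, RUNX1 and IRF2 to the shared unmarked sites stays open. Within marked regions the pairs overlapped 1.61 to 2.04 times as often as random draws, which took no account of region width.

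The higher share of kept enhancers among those bound by GATA1, NFE2 or RUNX1 was weighed against enhancer width and strength. Width is not excluded for all 6 log2 odds ratios: their lowest lower limit within width bins, 0.039 for RUNX1 in F0, did not exceed the 0.075 left over there when simulated binding followed width alone, but the lowest of the other 5, 0.22, did and argues against width as their whole cause. Strength is not excluded for all 6 either, since the lowest limit within score bins was -0.11, again for RUNX1 in F0, whose log2 odds ratio of 0.068 is consistent with stronger enhancers as its cause. The lowest limit of the other 5 was 0.065, for NFE2 in F0, above the 0.030 at most left over within score bins. This limit was not widened for the number of odds ratios weighed, so strength stays open for NFE2 in F0. The limits for GATA1 (0.33 in F0, 0.53 in A0), NFE2 in A0 (0.50) and RUNX1 in A0 (0.34) lay further above 0.030. They argue against strength alone as the whole cause for these. Width and score were not binned together, so both together stay open as the cause. The 5 were set apart only after the values of all 6 had been seen. For PU.1 in F0, -0.24 (-0.35 to -0.12) within width bins and -0.41 (-0.52 to -0.28) within score bins turned below 0, which is consistent with wider or stronger bound enhancers as the cause of the excess.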
